A study of Zea mays with 6 samples.

How the data were processed

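Maize leaf RNA from 6 samples, 3 treated with vehicle and 3 with 10-OPEA, was measured on the Affymetrix maize GeneChip. Per the labels' protocols, total RNA was labelled with biotin by a 3′ in vitro transcription kit at a core facility. The background correction, summarization and normalization are not given in the sources used here. The deposited table holds, per the file headers, a normalized signal per probe set and array, and its values are log2 signals, since the authors' fold change equals 2 to the power of the difference of their group means within 0.018%. The authors' table also gives group means as log2 values, a p-value, a t score and a linear fold ratio per probe set, per the file headers. The deposited p-value matches, within 0.00103, a Benjamini-Hochberg adjusted p rebuilt from the deposited t score. A second deposited table of log2 values was identical to the first.

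Samples were grouped by the treatment named in their labels. The array carries 17734 probe sets, and 113 control probe sets were left out of the tests, leaving 17621. No filter on dim signals was applied. Gene symbols and descriptions are those of the deposited annotation, which gives 1 gene for 12700 tested probe sets, several for 1371 and none for 3550. Of those with 1 gene, 11515 were found in the reference gene table. No gene was named from a probe set with several genes, except to say that it was shared. Probe sets of related genes can share signal, and this could not be separated here. For arrays, the number of samples limits the precision, and no read depth applies.

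The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as 10-OPEA minus vehicle, without a block, with Benjamini-Hochberg adjustment over all 17621 probe sets and a threshold of 0.05, with and without a fold of at least 2. Standard errors are the moderated ones. The 47 gene lists were defined by name patterns before the data were examined, and the 46 with at least 5 probe sets were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Only 4325 of the 17621 probe sets have a descriptive name of 1 gene, so the lists can miss members. Annotation terms with 10 to 300 probe sets were tested with camera. Adjusted p-values of lists and terms are over the lists or terms tested. By a rule set at the same point as the lists, the named genes are the 10 largest rises and the 10 largest falls among called probe sets whose groups do not overlap and that have a descriptive name, with 1 probe set per gene, of which only 5 falls were found. To these come up to 2 called members of each list that passed the set test or has at least 3 called members, and the members of the lipoxygenase pathway, 12-oxophytodienoate reductase and cystatin lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

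The procedure was tested on simulated data drawn from the means and spreads of the 17621 probe sets, with noise independent between probe sets. In the simulated comparison of 10-OPEA with vehicle, 73 of 100 probe sets changed by 1 on the log2 scale were called, and 96 of 100 changed by 2. Of 17371 unchanged probe sets 13 were called, which is 6.84% of all calls. A list of 50 probe sets shifted by 0.5 was called, and none of 46 unshifted lists was. The simulation gave both groups the same spread and held no split between vehicle arrays. In the data, the mean SD within the group was 0.227 for vehicle and 0.123 for 10-OPEA. The simulation therefore does not show how the tests behave with the split of the vehicle arrays described below.

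The alternatives fixed before the data were examined were quantile normalization, median centring, leaving out the dimmest 30% of probe sets, an intensity trend, array weights, leaving out probe sets of the cross-hybridizing types, 1 probe set per gene, the replicate number as a block and leaving out each array. A term for vehicle arrays 2 and 3, the Gapdh signal ratio as a covariate, vehicle array 1 as the only control, annotation terms with an estimated correlation and a narrower pathogenesis-related list were added after the data were seen.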

Results

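Gene expression was measured in maize leaves of the sweet corn variety Golden Queen after local treatment with 10-oxo-11-phytoenoic acid (10-OPEA), a cyclopentenone fatty acid made from linoleic acid through the 9-lipoxygenase pathway. Droplets of 2 mM 10-OPEA, or of the carrier alone (5% dimethyl sulfoxide with 0.1% Tween 20, called vehicle here), were placed on the partly emerged leaf 4 of plants 14 days old. The leaf tissue was collected 90 min later. Each group held 3 arrays of the Affymetrix maize GeneChip, and their number limits the precision of every value below. The median log2 signal of the arrays lay between 4.47 and 4.52. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples.

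The comparison asks which transcripts a leaf raises or lowers within 90 min of contact with 10-OPEA. The largest rise was that of opr1/2 (gene 732815), which encodes 12-oxo-phytodienoic acid reductase, a flavin enzyme that reduces oxo-oxylipins. Its log2 signal was 3.38 ± 0.08 (SD, n = 3) on the vehicle arrays and 10.06 ± 0.45 (SD, n = 3) on the 10-OPEA arrays. This is a 103-fold rise (log2 fold change 6.69, SE 0.21, limma adjusted p = 9.3e-05). Its vehicle signal lay close to the lower quartile of the arrays, which was 2.99 to 3.29, so the fold depends on the background of the array. The deposited annotation gives opr1 and opr2 as 1 entry, so the signal of the pair is not separated. Of 17621 probe sets, 77 were higher and 11 lower in 10-OPEA at an adjusted p under 0.05, and 66 and 2 of these changed at least 2-fold. Of the probe sets that rose, 26 rose at least 4-fold and 10 at least 8-fold. These counts moved widely with the arrays and settings used. Leaving out 1 array gave 24 (without vehicle array 3) to 2726 (without vehicle array 1) higher and 0 to 2872 lower, array weights gave 2557 and 2552, and quantile normalization of the deposited values gave 87 and 31. Without adjustment, 2320 were higher and 2165 lower at p under 0.05. The groups did not overlap for 25.7% of probe sets, where chance gives 10% for 3 against 3. Probe sets are not independent, and vehicle arrays 2 and 3 also stood apart in control signals (below), so this share does not measure the response to 10-OPEA alone. The authors' deposited table lists 70 probe sets with a p under 0.05, of which 62 were higher and 8 lower, and all 70 are among those called here.

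Of 47 probe sets for glutathione S-transferases, which join glutathione to electrophilic compounds, 8 rose, none fell and 39 did not pass the test. Adjusted over the list alone, 15 rose. The transcript of gst2 rose 10.8-fold (log2 fold change 3.44, SE 0.13, adjusted p = 9.8e-05), from a signal of 7.78 ± 0.15 to 11.22 ± 0.17 (SD, n = 3). The transcript of gst7 rose 3.20-fold (log2 fold change 1.68, SE 0.12, adjusted p = 0.0016). The other 6 probe sets belong to gst31, gst5 and the enzyme annotated as GST 22, and 4 of these 6 probe sets are for gst31, 1 of them shared with another gene, so they are not 6 separate genes. These 3 names were chosen after their values were seen. As a set, the list shifted up (camera adjusted p = 9.37e-05 with a preset correlation, adjusted p = 0.482 with an estimated correlation). Of 11 probe sets for sulfur assimilation and glutathione synthesis, 1 rose, and 6 rose when adjusted over the list alone. It was gsh1, which encodes γ-glutamylcysteine synthetase, the first enzyme of glutathione synthesis (log2 fold change 1.20, SE 0.14, adjusted p = 0.017).

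Of 24 probe sets for cytochrome P450s, monooxygenases that oxidize hormones, defence compounds and foreign chemicals, 3 rose, none fell and 21 did not pass. Adjusted over the list alone, 3 rose and 1 fell. LOC100279819 rose 13.6-fold (log2 fold change 3.76, SE 0.19, adjusted p = 0.000402). LOC100272761 rose by a log2 fold change of 3.02 (SE 0.18, adjusted p = 0.000691), from a vehicle signal (3.54) close to the lower quartile of the arrays, so its size depends on the background. LOC100279598, chosen after its value was seen, had a log2 fold change of 2.10. The list as a whole did not pass the set test (camera adjusted p = 0.376), and its median (-0.05) and mean (0.34) differed in sign. Of 26 probe sets for UDP-glycosyltransferases none passed, and 3 rose when adjusted over the list alone (camera adjusted p = 0.122).

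Of 8 probe sets for 12-oxophytodienoate reductases, 2 rose and 6 did not pass. Adjusted over the list alone, 4 rose and 1 fell. Besides opr1/2, a probe set for opr3 rose (log2 fold change 2.82, SE 0.37, adjusted p = 0.0294). Its mean vehicle signal of 2.66 lay below the lower quartile of every array, so the size of this rise depends on the background. The other probe set for opr3 had a log2 fold change of 0.54 (adjusted p = 0.136). The called opr3 probe set is of the cross-hybridizing types, so signal shared with other reductases such as opr1/2 could not be separated from its rise. The values for opr5, opr6 and the pair of opr8 probe sets were 0.45, 0.05, -0.12 and -0.47, none past the threshold. The probe set that the reference names opr7 (annotated as pco088243a) had a value of -0.32 (SE 0.10, adjusted p = 0.161) and is the one that fell when adjusted over the list alone. The list shifted up (camera adjusted p = 0.0308, adjusted p = 0.482 with an estimated correlation). None of 14 lipoxygenase pathway probe sets passed, at the adjusted threshold or adjusted over the list alone (camera adjusted p = 0.878, median -0.08, mean 0.013). Among them aos1, for allene oxide synthase, had a log2 fold change of 0.62 (SE 0.27, adjusted p = 0.201), LOX4 0.52, lox10 0.04 and aoc1 -0.43. None of 11 cystatin probe sets, for inhibitors of cysteine proteases, passed either (camera adjusted p = 0.439, median -0.06, mean 0.22). The largest value in that list was 1.69 (SE 0.51, adjusted p = 0.161), for a probe set shared by psei1 and psei2, and there vehicle arrays 2 and 3 lay below vehicle array 1 by a log2 difference of -1.91. None of 18 jasmonate response probe sets passed, and 1 rose when adjusted over the list alone (camera adjusted p = 0.0695).

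Of 80 probe sets for heat shock proteins and chaperones, 3 rose and 77 did not pass. Adjusted over the list alone, 6 rose and 7 fell. The 3 were the class I heat shock protein LOC100191552 (log2 fold change 2.74, SE 0.28, adjusted p = 0.00839), hsp18a (2.24, SE 0.22, adjusted p = 0.00809) and the class IV protein LOC100282088 (0.79), the last chosen after its value was seen. The list as a whole did not pass the set test (camera adjusted p = 0.868), and its median (-0.08) and mean (0.03) differed in sign. LOC100281011, a type-A response regulator of the kind that cytokinin induces, had a log2 fold change of 1.46 (SE 0.13, adjusted p = 0.00571). It was the only called member of 17 probe sets for cytokinin and response regulators, of which 6 rose and 1 fell when adjusted over the list alone. That list shifted up (camera adjusted p = 0.00127, adjusted p = 0.482 with an estimated correlation). LOC100284800, for gibberellin 20-oxidase, an enzyme of gibberellin synthesis, rose 6.07-fold (log2 fold change 2.60, SE 0.15, adjusted p = 0.00057). It was the only called member of 20 probe sets for gibberellin and brassinosteroid, of which 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.696). The EF-hand calcium-binding protein gene AC225718.2_FG006 rose 5.75-fold (log2 fold change 2.52, SE 0.14). It was the only called member of 76 calcium signalling probe sets, of which 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.334). LOC100284758, annotated as embryonic abundant protein-like, rose (log2 fold change 4.03, SE 0.34, adjusted p = 0.004), as did the hydrolase LOC100216915 (log2 fold change 2.93, SE 0.20). Their vehicle signals, 3.51 and 3.74, were also near the lower quartile of the arrays, so the sizes depend on the background.

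**Figure D1:**
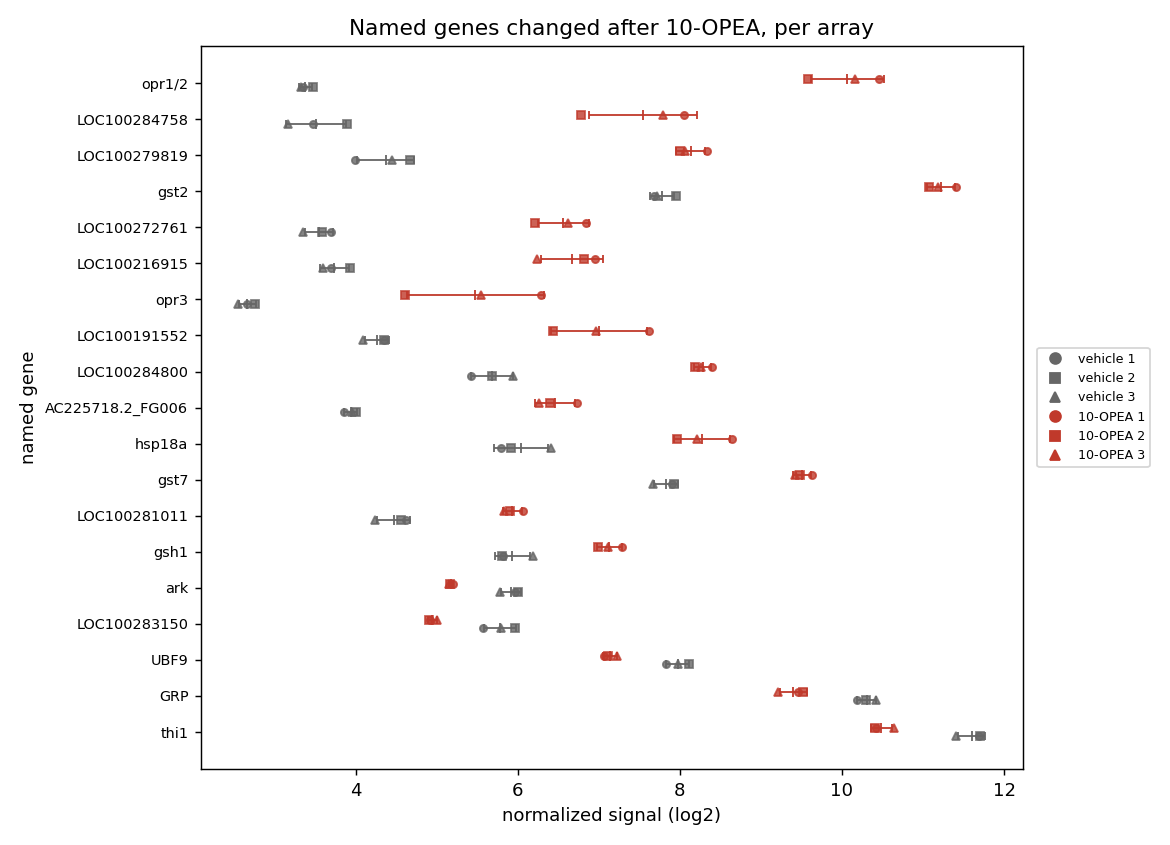
Normalized log2 signal (x axis) of the 19 named genes past the threshold (y axis). Each point is an array, with vehicle in grey and 10-OPEA in red, and bars give the mean ± SD of 3 arrays. The opr1/2 signal is 3.38 in vehicle and 10.06 in 10-OPEA, and the groups do not overlap for any gene shown.

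The transcript of thi1, for thiamine biosynthesis, fell by 1.11 on the log2 scale (SE 0.13, adjusted p = 0.0142), from 11.60 ± 0.17 to 10.49 ± 0.13 (SD, n = 3). The glycine-rich RNA-binding protein gene GRP fell by 0.91 (SE 0.12), the ubiquitin gene UBF9 by 0.84, the gene for the ribosome biogenesis protein NIP7 (LOC100283150) by 0.83 and the receptor-like kinase gene ark by 0.74. The last was the only called member of 61 probe sets for receptor and MAP kinases, at this threshold or adjusted over the list alone (camera adjusted p = 0.952). GRP and UBF9 are also annotated as structural constituents of the ribosome. So is pco098394, chosen after its value was seen, which fell by 0.86 (SE 0.11, adjusted p = 0.0267). None of them is in the ribosomal protein list, which was matched by name. Of the 308 probe sets in that list, none passed the threshold, and 64 fell and 14 rose when adjusted over the list alone. Their median log2 change was -0.16 against a median of -0.08 over all probe sets, and the list shifted down (camera adjusted p = 0.0308, adjusted p = 0.482 with an estimated correlation). The call was lost without vehicle array 1 (adjusted p = 0.726), where the median was -0.14 against -0.11 over all probe sets. It was lost without 10-OPEA array 2 (adjusted p = 0.0591), where the medians were -0.15 and -0.09. Array weights (adjusted p = 0.37, medians -0.13 and -0.10) and the replicate block (adjusted p = 0.106, medians -0.16 and -0.08) ended the call as well. The adjusted p of fry, which tests the list against no change rather than against other probe sets, was 0.0721.

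Control signals set vehicle arrays 2 and 3 apart from the other 4. The signal at the 3′ end of Gapdh exceeded that of its middle part by 7.38 and 7.02 log2 units on these arrays, and by 3.48 to 4.59 on the others. The mean log2 signal of the bioB spike-in was 4.64 to 5.20 on the others, and at least 1.30 above these on both vehicle arrays. The first principal component held 76.0% of the variance, with scores of 40.9 and 44.4 for vehicle arrays 2 and 3, -7.54 for vehicle array 1 and -36.8 to -14.5 for the 10-OPEA arrays. Vehicle array 1 correlated at 0.991 to 0.994 with the 10-OPEA arrays and at 0.984 and 0.982 with vehicle arrays 2 and 3, across probe sets, which are not independent replicates.

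**Figure D2:**
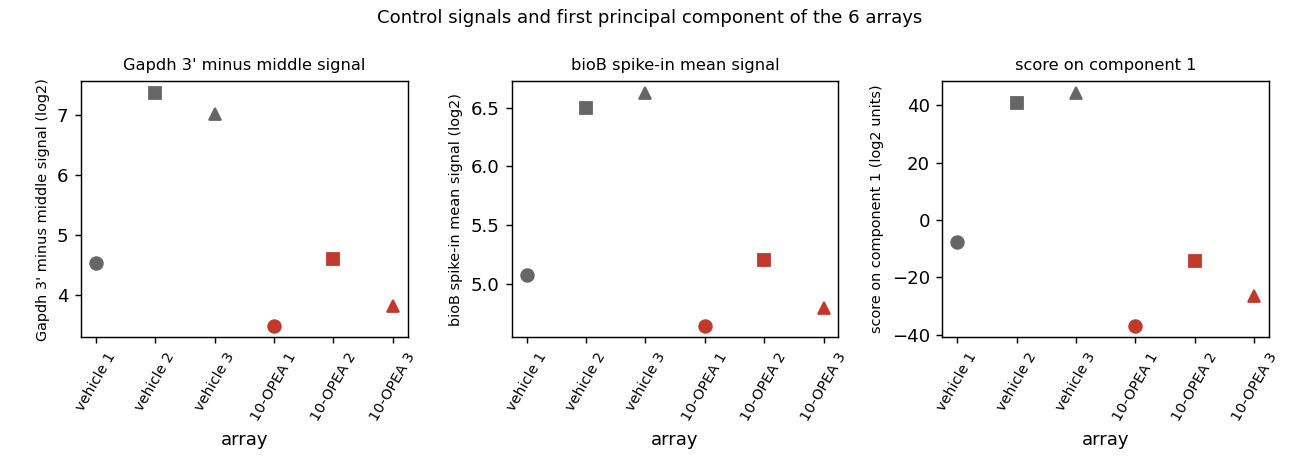
Gapdh 3′ minus middle signal (log2), mean bioB spike-in signal (log2) and score on the first principal component (y axes) for each of the 6 arrays (x axes). Each point is an array, with vehicle in grey and 10-OPEA in red. Vehicle arrays 2 and 3 lie at 7.38 and 7.02 in the Gapdh panel and the other 4 arrays at 3.48 to 4.59.

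The size of several other list shifts differed between the vehicle arrays. In all, 10 of 46 lists tested passed the set test, 7 up and 3 down, none with an estimated correlation. By fry, the glutathione S-transferase, 12-oxophytodienoate reductase and response regulator lists passed (adjusted p = 0.0177, 0.0121 and 0.0121), and the other 7 did not. The response regulator list lost its camera call at an estimated correlation of -0.029, below the preset 0.01. A call lost with an estimated correlation thus does not by itself show correlated members. The sulfur and glutathione synthesis list had a median log2 change of 0.61 (camera adjusted p = 0.00015, adjusted p = 0.482 with an estimated correlation), but 0.11 against vehicle array 1 alone. There vehicle arrays 2 and 3 lay below vehicle array 1 by a median of -0.64. The 19 bundle sheath markers had a median of 0.27 against all vehicle arrays and 0.14 against vehicle array 1 (camera adjusted p = 0.00127, adjusted p = 0.482 with an estimated correlation), with none called and 9 higher when adjusted over the list alone. The 81 antioxidant enzyme probe sets had medians of 0.16 and 0.04 (camera adjusted p = 0.00214, adjusted p = 0.482 with an estimated correlation), with none called and 1 higher adjusted over the list alone. Outside this name-based list, umc2199, annotated with protein disulfide oxidoreductase activity and chosen after its value was seen, rose (log2 fold change 1.80, SE 0.18). Histones (56 probe sets, camera adjusted p = 0.0474) and seed storage proteins (52 probe sets, camera adjusted p = 0.009) shifted down with none called, at this threshold or adjusted over the list alone, and both gave an adjusted p = 0.722 with an estimated correlation. Their medians were -0.19 and -0.17 against all vehicle arrays, and -0.06 and -0.04 against vehicle array 1. The 46 probe sets of the pathogenesis-related list shifted up (camera adjusted p = 0.0308, adjusted p = 0.482 with an estimated correlation), with none called. However, 20 of the 46 are methionine or cystathionine enzymes that its search pattern also matched, and without them the adjusted p was 0.425 and the median -0.01. The pattern also missed called rises with defence annotations, chosen after their values were seen. They include LOC100274400, annotated with chitinase activity (log2 fold change 4.67, SE 0.36), and pco080661a, annotated with systemic acquired resistance (3.19, SE 0.46, adjusted p = 0.043). Their vehicle signals, 3.23 and 3.01, lay near the lower quartile of the arrays, so the sizes depend on the background. The glutathione S-transferase, 12-oxophytodienoate reductase, response regulator and ribosomal protein lists had medians of 0.12, 0.28, 0.21 and -0.18 against vehicle array 1, and 0.10, 0.25, 0.19 and -0.16 against all vehicle arrays. The median over all probe sets was -0.015 and -0.08 in that order. The ribosomal median differed from it by -0.16 against vehicle array 1, -0.08 against all vehicle arrays and -0.028 without vehicle array 1. The ribosomal shift against other probe sets therefore also differed between the vehicle arrays. A model term for vehicle arrays 2 and 3, chosen after seeing the data, leaves vehicle array 1 alone as the control level. With this term, 7 of the 10 lists stayed past the threshold at the preset correlation, a result that rests on 1 control array. These 7 include the sulfur and glutathione synthesis, bundle sheath and antioxidant lists, each with an adjusted p = 0.0177 (4.6e-05 to 0.542, 0.000529 to 0.616 and 0.000817 to 0.482 over their alternatives). The histone, seed storage and pathogenesis-related lists were lost with the term.

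**Figure D3:**
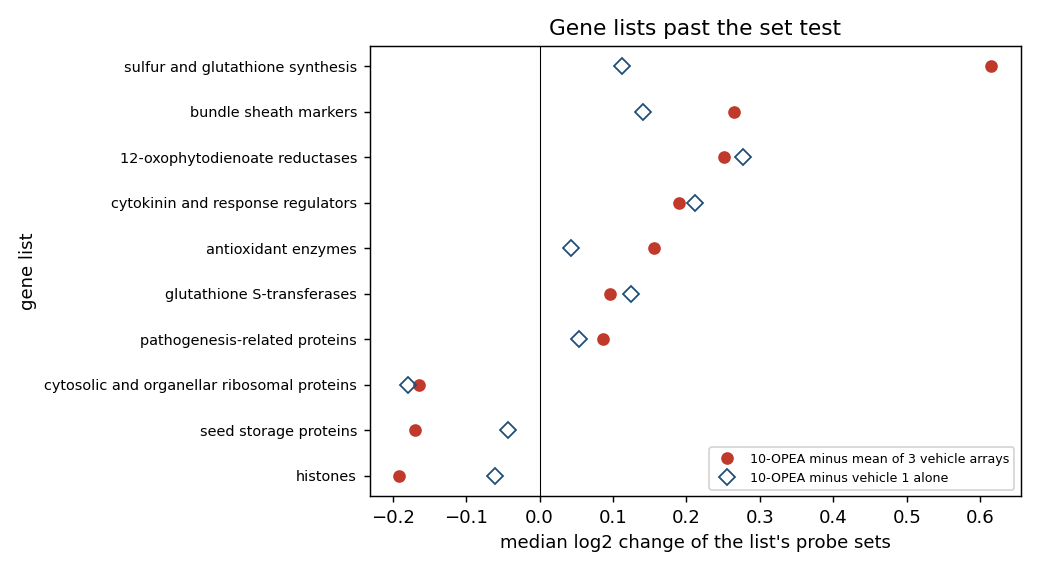
Median log2 change of the probe sets (x axis) of the 10 gene lists past the set test (y axis). Filled circles are 10-OPEA minus the mean of the 3 vehicle arrays, and open diamonds are 10-OPEA minus vehicle array 1 alone. The sulfur and glutathione synthesis list lies at 0.61 and 0.11, and ribosomal proteins at -0.16 and -0.18. Over all probe sets, which are not drawn, the medians were -0.08 and -0.015 in the same order.

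Of 630 annotation terms, 204 passed the set test, 197 up and 7 down, none with an estimated correlation. The 3 lowest p-values were those of photosystem II assembly, the pentose-phosphate shunt and thylakoid membrane organization. Photosystem II assembly, with 49 probe sets, had a median log2 change of 0.62 (camera adjusted p = 3.18e-15, adjusted p = 0.46 with an estimated correlation), against 0.21 relative to vehicle array 1, and none of its probe sets was called. Thylakoid membrane organization, with 50 probe sets, had medians of 0.80 and 0.17 (camera adjusted p = 3.29e-12, adjusted p = 0.46 with an estimated correlation). The fixed list of photosystem and light harvesting genes, with 56 probe sets, did not pass (camera adjusted p = 0.59), with none called and 5 higher and 7 lower when adjusted over the list alone. The model term for vehicle arrays 2 and 3 leaves vehicle array 1 alone as the control level. With that term, 76 annotation terms passed at the preset correlation, of which 63 are among the 204 with the same direction. With the Gapdh ratio as a covariate instead, 21 passed, of which 3 are among the 204 with the same direction. Photosystem II assembly and thylakoid membrane organization stayed up with the term for vehicle arrays 2 and 3, with medians of 0.21 and 0.17. Their camera adjusted p reached 0.46 and 0.747 over their alternatives. That term leaves differences in control signals between vehicle array 1 and the 10-OPEA arrays. The Gapdh ratio was 3.48 and 3.81 on 10-OPEA arrays 1 and 3, and 4.53 on vehicle array 1. On 10-OPEA array 2, at 4.59, the photosystem II assembly median against vehicle array 1 was 0.09. These shifts therefore cannot be told apart from such differences.

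With the term for vehicle arrays 2 and 3, 32 were higher, all among the 77, and none lower, with 485 and 489 at an unadjusted p under 0.05. The 45 rises lost there had a median of 0.998 times their change without the term, with an SE 1.31 times as large, and the 11 falls 0.887 times their change, with an SE 1.28 times as large. The term leaves vehicle array 1 alone as the control level, and calling with all arrays needs that array near the other vehicle arrays. Ratios near 1 were therefore largely set by the calling and do not show that the changes hold. Left out in turn, vehicle arrays 1, 2 and 3 gave 2726, 28 and 24 higher and 2872, 0 and 1 lower, and 10-OPEA arrays 1, 2 and 3 gave 33, 52 and 34 higher and 0, 1 and 0 lower. Where none was lower, 840 to 1075 were at an unadjusted p under 0.05. The Gapdh ratio as a covariate, chosen after seeing the data, gave 31 higher and none lower, with 430 and 458 unadjusted. Those unadjusted counts, like those with the term, are close to what chance alone gives at p under 0.05 over 17621 probe sets. The 50 rises lost with the Gapdh covariate had 0.928 times their change and an SE 1.47 times as large. Of the 19 named genes past the threshold, 9 stayed past it with the term, among them opr1/2 (adjusted p = 0.00116, and 1.47e-05 to 0.274 over its alternatives, the highest against vehicle array 1 alone, with 2 residual degrees of freedom and a log2 fold change of 6.72), gst2, gst7, both leading P450 genes and LOC100284800. The glutathione S-transferase probe sets called higher numbered 4 with the term, 15 without vehicle array 1, 3 without vehicle array 2 or 3, and 2 without 10-OPEA array 1 or 3. The heat shock probe sets numbered 1, 14, 0 and 1, and 2 and 0, in the same order, and the opr3 call was lost with the term (adjusted p = 0.246, and 0.00578 to 0.579 over its alternatives). There its log2 fold change was 2.82 with an SE of 0.55, against 2.82 with an SE of 0.37 without the term, so the call ended with the larger error. The calls of LOC100284758 (adjusted p = 0.0582), LOC100281011 (adjusted p = 0.0601), gsh1 (adjusted p = 0.0884) and LOC100191552 (adjusted p = 0.108) were lost with the term as well. Their log2 fold changes there were 4.07 (SE 0.50), 1.32 (SE 0.17), 1.32 (SE 0.19) and 2.66 (SE 0.40), and over their alternatives their adjusted p ran from 0.00134 to 0.535. The P450 probe sets numbered 3 with the term and 7 without vehicle array 1. No fall passed with the term, where the 5 named falls had log2 fold changes of -1.20 to -0.63.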

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

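The 3′ to middle ratio and the count of probe sets at vehicle level were tests chosen after the results were seen. Among 26 control probe sets for maize transcripts, which the comparison does not use, 4 had all 3 10-OPEA arrays above all 3 vehicle arrays, where chance would give 1.3. With 1 lying the other way, the groups did not overlap for 19.2% of these controls, which is no more than the 25.7% of all probe sets tested, so the controls do not stand out from the rest of the array. The middle part of cyclophilin was higher in 10-OPEA by 0.93 on the log2 scale, and the middle, 5′ and 3′ parts of ubiquitin by 0.73, 0.21 and 0.15. Most of the cyclophilin difference came from vehicle arrays 2 and 3, with signals of 9.07 and 8.63. Vehicle array 1, at 9.99, lay close to the 10-OPEA arrays, at 10.00 to 10.25.

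Vehicle arrays 2 and 3 stood apart from the other 4 arrays. The 3′ minus middle signal of Gapdh, cyclophilin and ubiquitin was higher on both than on each of the other 4, with gaps of at least 2.43, 0.96 and 0.35 log2 units, which is consistent with a difference in RNA integrity or labelling. That vehicle array 1 was a mislabelled treated leaf is argued against by 10 of the 19 probe sets at least 8-fold higher when it was left out, where it lay close to the other vehicle arrays and far from 10-OPEA, opr1/2 among them (3.35). A test planned before its result was seen, the median position of vehicle array 1 over these 19, gave 0.0754 with quartiles of -0.029 and 0.88, and did not decide alone, since the other 9 lay near the 10-OPEA level. What caused the difference between vehicle arrays, and whether the leaves themselves differed, stays open.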

How the results depend on the processing

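The groups of all 88 called probe sets did not overlap, so leaving out arrays, array weights and the term could not turn their direction. With the Gapdh covariate, which could, all 88 kept it. The main counts, 77 higher and 11 lower (66 and 2 at least 2-fold), were moved by over 1.5 times in these settings, and the cause was not tested unless given. Array weights gave 2557 and 2552 (639 and 103 at least 2-fold), with a weight of 8.89 for 10-OPEA array 3. Quantile normalization gave 31 lower, 7 of them at least 2-fold. Leaving out 1 array gave 24 to 2726 higher and 0 to 2872 lower (23 to 823 and 0 to 142 at least 2-fold), the highest without vehicle array 1. The replicate block gave 1016 and 469 (367 and 40 at least 2-fold). The deviations of samples with the same number correlated at 0.49, 0.36 and -0.10, and vehicle 3 correlated best with 10-OPEA 2 (0.38). With 3 samples per group and vehicle arrays 2 and 3 apart from vehicle array 1, this cannot tell whether same-numbered samples were paired. Apart from fry and the estimated correlation, the alternatives fixed beforehand kept 7 to 10 of the 10 lists past the set test. Quantile normalization, the dim filter, leaving out cross-hybridizing types and leaving out vehicle array 2 each kept 7. The alternatives named from here on, but for fry and the estimated correlation of lists, were chosen after seeing the data. The term for vehicle arrays 2 and 3 gave 32 and 0 (31 and 0 at least 2-fold), and the Gapdh covariate 31 and 0 (31 and 0 at least 2-fold), with 430 and 458 unadjusted. Such unadjusted counts are close to what chance alone gives at p under 0.05. The rises lost had medians of 0.998 and 0.928 times their change and an SE 1.31 and 1.47 times as large, so these calls ended mainly with the larger error. Calling with all arrays needs vehicle array 1 near the other vehicle arrays, so the ratio with the term does not show that the rises hold. Vehicle array 1 as the only control gave 0 and 0 (0 and 0 at least 2-fold), with 651 and 715 unadjusted, the lone array being assumed to vary like the 10-OPEA arrays. With 1 control array and 2 residual degrees of freedom, this says nothing about the stability of the calls. Of 10 lists past the set test, fry called 3 and an estimated correlation 0. The Gapdh covariate and vehicle array 1 alone each called 6 of all lists, 4 of them among the 10. Seed storage proteins reversed with the Gapdh covariate, to a median of 0.012. Of all annotation terms, 76 passed with the term, 21 with the Gapdh covariate, 70 against vehicle array 1 alone and 0 with an estimated correlation, of which 63, 3, 58 and 0 are among the 204. The 19 named genes past the threshold stayed past it in 241 of 322 values. Of 31 named probe sets not past it, 14 passed in at least 1 alternative. The second deposited table held identical values and the values were already on a log scale, so those alternatives were not run. Signal over background could not be set, as no detection calls were used.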

Other observations

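The tests in this part on the called probe sets, annotation terms, ribosomal proteins, heat shock proteins and other splits were chosen after the results were seen. Genes outside the naming rule, chosen after their values were seen, rose as well. LOC100274400, annotated with chitinase activity, had a log2 fold change of 4.67, saf1 (safener induced1) 2.30, expa1 (an α-expansin, which loosens cell walls) 1.45, the gene for WRKY69 1.44 and O-succinylhomoserine sulfhydrylase (LOC100285862) 1.62. The vehicle signals of LOC100274400 (3.23) and WRKY69 (2.94) lay within or below the range of the lower quartiles of the arrays, so their sizes depend on the background. The deposited annotation marks 6 probe sets as responding to cyclopentenones, the chemical class of 10-OPEA. Of these 2 rose and none fell, with log2 changes from -0.73 to 4.03 over the 6.

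The rises were set against the split of the vehicle arrays. A test written before its result was seen took the 77 rises with the lowest p when vehicle array 1 was left out: their rise against vehicle array 1 was a median of 0.198 of that against vehicle arrays 2 and 3 (quartiles 0.147 and 0.381), so most rises found that way followed the split, and only 17 of them are among the 77 called with all arrays. For these 77 called probe sets, a test added after that result gave 1.03 (quartiles 0.951 and 1.10), but calling with all arrays needs vehicle array 1 near the other vehicle arrays, so this decides nothing. With the term for vehicle arrays 2 and 3, which leaves vehicle array 1 alone as the control level, 32 of the 77 passed, and how far the split bears on the called rises stays open. The real grouping called 88 probe sets and the highest of the other 9 splits called 0, so 1 of 10 splits reached 88, and so few splits cannot give a share under 0.05.

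Annotation terms shifted up had a median change against vehicle array 1 that was 0.2999 of that against all vehicle arrays, over 196 terms (quartiles 0.205 and 0.408). The split of the vehicle arrays, as a source of much of their size, would give such a ratio. Of the 204 terms, 63 stayed past the threshold with the term for vehicle arrays 2 and 3, and 3 with the Gapdh covariate. Ribosomal proteins had a median of -0.18 against vehicle array 1 (quartiles -0.36 and 0.00336), which lay below that of all probe sets by -0.16, while without vehicle array 1 the difference from all probe sets was -0.028. Their adjusted p ran from 1.32e-18 to 0.726 over all alternatives, with 5.31e-14 with the term and the highest without vehicle array 1, so the shift against other probe sets depends on which vehicle arrays serve as control. The Gapdh ratio of 10-OPEA array 2 (4.59) lay near that of vehicle array 1 (4.53). In that 10-OPEA array, the median against vehicle array 1 was -0.20 for ribosomal proteins and 0.09 for photosystem II assembly. For the 77 called rises it was 1.46, but these were called from the same arrays. Their groups do not overlap, so that value was largely set by the calling and does not show that the rises hold. Whether ribosomal protein transcripts respond to 10-OPEA stays open.

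All 3 heat shock genes that rose encode small heat shock proteins. The hypothesis that the rise belongs to this class was tested on the 80 probe sets of the list. The 21 small ones had a mean log2 change of 0.20 and a median of -0.12, and the other 59 a mean of -0.03 and a median of -0.05. The difference of means did not pass a two-sided permutation test (p = 0.111, 100000 resamples), in which genes are not independent replicates.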
